A study of Arabidopsis thaliana with 14 samples.

How the data were processed

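The 14 libraries came from 7-day-old whole seedlings of Arabidopsis thaliana, ecotype Col-0, of a line that expresses a FLAG-tagged ribosomal protein L18 (35S:HF-RPL18B). Seedlings spent 2 h in argon (hypoxia) or 2 h in air (normoxia), in the same low light, per the labels' protocols. 4 kinds of RNA were sequenced. Total mRNA is the poly(A)+ RNA of the cleared extract. Polysomal mRNA is poly(A)+ RNA pulled down with tagged ribosomes by TRAP (translating ribosome affinity purification, an antibody capture of the tag). Footprints are the stretches of mRNA that ribosomes shield from nuclease. They came from ribosomes spun through sucrose (conventional footprints) or from ribosomes captured by TRAP (TRAP footprints). Total mRNA, polysomal mRNA and conventional footprints have 2 libraries per condition. TRAP footprints have 1 per condition. The series design calls the libraries biological replicates. The labels do not say how the plant material was divided, so p-values measure the spread between these samples.

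The authors deposited 8 tables of RPKM values, per the file names: reads per kilobase of feature and per 1e6 aligned reads. The tables cover coding sequences (CDS) per gene, exons per gene, whole genes, 5' UTRs, 3' UTRs, introns, upstream open reading frames (uORFs) and intergenic intervals. CASAVA 1.8, TopHat 1.3.1 and the TAIR10 genome are named in the submitters' processing notes, with no role given. The counting tool, its strand setting and the treatment of reads with several alignments are not given in the sources used here. Each library has an unmarked column and a column marked multi. The suffix is not defined in the tables. The unmarked columns were used throughout, and the multi columns served as an alternative. Reads of a gene and of a gene that overlaps it cannot be told apart, so such genes are reported as uncertain. The same holds for genes with many more reads in the multi columns.

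Per the tables, RPKM values are whole multiples of the value of 1 read. The denominators and whole reads were therefore recovered from the low values. In the 6 tables with interval coordinates 100% of the values above 0 came out whole, at a tolerance of 0.001 reads. CDS lengths are not in the tables. They were solved as the smallest length that makes every value of the gene whole. A length was found for all 25581 CDS genes with a read. Among the 18907 genes with at least 100 reads, 93.9% of the solved lengths were multiples of 3. The denominators were 19.6 to 30.7 M reads (1 M is 1e6 reads) in conventional footprints and 8.79 to 8.83 M in TRAP footprints. They were 7.44 to 17.3 M in total mRNA and 7.64 to 15.1 M in polysomal mRNA. Nuclear CDS reads per library ranged from 5.80 to 13.3 M. Intervals on shares of reads are 95% Wilson binomial intervals and cover counting error only.

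Gene names came from a reference table of the same species, matched on locus identifiers. Of 27416 CDS identifiers, 26719 matched. All matched nuclear intervals (100%) overlapped the reference interval of the gene, and 50.2% shared a start or an end. Coordinates are those of the deposited tables.

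The design written before the data were examined assumed counts and a quasi-likelihood count test. The files hold RPKM, so the test written there for that case was used: limma 3.58.1 in R 4.3.3, with an intensity trend (limma-trend), on log2(RPKM + 0.5). Fold changes are on that scale, which understates the change of low genes. Nuclear genes with at least 1 RPKM in 2 or more of 12 libraries were tested, 18701 of 27206. The 88 plastid and 122 mitochondrial genes were left out of the fit. Poly(A) selection in total and polysomal mRNA, and none in footprints, makes them not comparable between pools. The fit had 6 groups (3 pools by 2 conditions) and 6 residual degrees of freedom, with 4.91 prior degrees of freedom. TRAP footprints entered no fit. Contrasts were hypoxia against normoxia in each pool, the 3 differences of these effects between pools (interactions), and the 3 differences between pools in normoxia. P-values were adjusted by Benjamini-Hochberg over the genes tested, with a threshold of 0.05. The smallest two-sided p of an exact permutation test of 2 against 2 libraries is 0.333, so no such test was used.

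The median gene was shifted in several contrasts. The shift in log2 was -0.14 in total mRNA, -0.22 in polysomal mRNA and -0.49 in footprints. It was -0.03, -0.32 and -0.29 for the interactions of polysomal over total mRNA, footprint over total mRNA and footprint over polysomal mRNA. In normoxia it was -0.07, -0.50 and -0.44 for the same pairs of pools. Changes are printed relative to this median. P-values come from the values as deposited. A fit after scaling the libraries by the median of ratios stands beside the main one where it moves the share of higher calls.

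Genes named in the text followed a rule written before the data were examined. It takes the 10 largest rises and 10 largest falls per hypoxia contrast among called genes of at least 10 CPM whose libraries do not overlap between groups, and 5 of each in the other contrasts. It adds the 3 members of each list with the highest level and the 2 with the lowest adjusted p, the 3 largest features in each direction, RPL18B, and ADH1, PDC1, HB1, SUS4, LBD41, PCO1, PCO2, HRE1 and HRE2. Other members that make up a count of 5 or fewer were chosen after their values were seen.

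Before the data were examined, 16 gene lists were fixed, of which 412 members were used: core anaerobic genes, glycolysis and fermentation enzymes, early stress regulators, ethylene and oxygen sensing, heat shock proteins and factors, jasmonate genes, sugar starvation genes, cytosolic ribosomal proteins, translation factors, nuclear photosynthesis genes, cell wall and aquaporin genes, histones and cell cycle, circadian clock, root-enriched genes, known uORF genes and reference genes. A member was left out where the reference gives a symbol and neither it nor a synonym matches the expected one. This left out PGK3, PGAM1, PGAM2, RPL18B, SAMDC1 and NMT2. Members known in the reference by the locus identifier alone were kept, as were those listed without an expected symbol. Lists were tested with camera in limma, with a preset correlation of 0.01, adjusted over the 16 lists of a contrast. Camera with an estimated correlation was run beside it. Counts of members are given over all genes tested and adjusted over the list alone. The core anaerobic genes had been chosen in earlier work on hypoxic seedlings, so their direction is not independent evidence. Some genes belong to several lists and count in each. The core list shares ADH1, PDC1, PDC2, SUS4 and PFK6 with the glycolysis and fermentation enzymes. It shares HRE1, HRE2, PCO1, PCO2, ETR2 and ACO1 with ethylene and oxygen sensing, RBOHD with early stress regulators and JAZ3 with jasmonate genes. GBF6, bZIP1 and BZIP53 are both sugar starvation and known uORF genes. Results of lists that share genes are not independent.

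For UTRs, uORFs and introns, the log2 ratio of feature to CDS of the same gene was fitted with limma, for features with at least 10 reads in 2 or more libraries and a pseudocount of 0.5. The TRAP footprints were compared with the mean of the conventional footprints of the same condition. Correlations used genes of at least 1 CPM, and lists used the 18701 genes tested. The median of each list was placed among those of 10000 random lists of the same size, matched on level in 20 bins. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1 served for the tables, and matplotlib 3.10.9 for the plots.

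The steps were tested on simulated data. For total mRNA, in a simulation with 18408 genes, 33% of genes changed 4-fold and 1% of genes changed 2-fold were called, with 2 unchanged genes called. For the interaction of polysomal over total mRNA, 0% of either were called. The list test called a list of moved genes and did not call a list of unmoved genes. The simulated genes were drawn independently, so this could not show how the preset correlation serves for lists of correlated genes. The ratio test on 2000 features called 87% of features changed 8-fold, with 11 unchanged features called. Its ratios were drawn from normal distributions, without reads, a pseudocount or interval lengths, so it does not cover their effects.

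The alternatives were median-of-ratios scaling, all exons in place of the CDS, organelle genes in the fit, pseudocounts of 1 and 0.1, no filter, a minimum log2 change of 1, the compared pools only, the replicate number as a block, and each library left out. Chosen after the data were seen were limma-voom on recovered reads, the multi columns, the block with scaling, and footprint normoxia library 1 left out with scaling. A 0.1 pseudocount in the feature tests, TRAP lists against footprint normoxia library 2 alone, and gene lists in the normoxia contrasts without library 1 were added as well.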

Results

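Messenger RNA abundance, polysome association and ribosome footprints were measured in the same line of Arabidopsis seedlings after 2 h of hypoxia or normoxia. Total mRNA, polysomal mRNA and conventional footprints had 2 libraries in each condition, and TRAP footprints had 1. Nuclear coding reads per library numbered 10.1 to 13.3 M in conventional footprints and 5.80 to 6.08 M in TRAP footprints. They numbered 5.83 to 13.3 M in total mRNA and 6.62 to 12.8 M in polysomal mRNA. Across genes, the log2 values of the 2 libraries of a group correlated with r from 0.931 to 0.962. The tagged gene, AT3G05590 (RPL18B, listed as RPL18, chromosome 3, 1621457 to 1623014), was at 3034 ± 133 RPKM in normoxic total mRNA (mean ± SD, n = 2) and at 13830 ± 4660 RPKM in normoxic polysomal mRNA. In hypoxia it was at 2242 ± 7.36 RPKM in total mRNA and 7968 ± 587 RPKM in polysomal mRNA. Conventional footprints gave 1103 ± 4.06 RPKM in hypoxia and 1546 ± 23.4 RPKM in normoxia. The TRAP footprint libraries gave 3161 RPKM in hypoxia and 3628 RPKM in normoxia. Reads of the transgene and of the native gene were not separated.

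The first comparison asks which transcripts changed in abundance under hypoxia. ADH1, PDC1, SUS4, LBD41, PCO1 and PCO2 rose in total mRNA. ADH1 (AT1G77120, chromosome 1, 28975394 to 28977417), the alcohol dehydrogenase of fermentation, went from 8.84 ± 0.88 to 929 ± 125 RPKM (n = 2, log2 +6.77 ± 0.53 SE, limma adjusted p = 0.000118). PDC1 (AT4G33070, chromosome 4, 15952289 to 15954771), a pyruvate decarboxylase, went from 3.52 ± 1.84 to 600.1 ± 133 RPKM (log2 +7.42 ± 0.91). SUS4, a sucrose synthase, rose by log2 +6.51 ± 0.34 and the transcription factor LBD41 by log2 +7.13 ± 0.50. The plant cysteine oxidases PCO1 (AT5G15120), at log2 +5.92 ± 0.41, and PCO2 (AT5G39890), at log2 +6.04 ± 0.39, take part in oxygen sensing. The largest rise was that of AT5G10040, an uncharacterized protein, from 0.19 ± 0.27 to 377 ± 62.3 RPKM (log2 +9.28 ± 0.57).

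In total mRNA 182 of 18701 nuclear genes were called higher and 55 lower by limma. The other rises named by the rule were AT4G10265 and AT4G10270, wound-responsive family proteins, the aquaporin-like NIP2;1, SRO4, AT2G17850 and the calmodulin-like CML38, at log2 +6.83 to +8.24. HB1, a hemoglobin, rose by log2 +4.14 ± 0.34. The ethylene response factors HRE2 (ERF71) and HRE1 (ERF73) rose by log2 +5.16 ± 0.55 and +3.62 ± 0.66. The largest falls were those of AT5G57760 (log2 -3.56 ± 0.67) and of AT5G46330 (FLS2, the flagellin receptor), from 22.3 ± 10.5 to 2.52 ± 0.60 RPKM (log2 -2.71 ± 0.39). The root hair genes RHS12, RHS18 and RHS19 and the expansin EXPA18 fell by log2 -2.49, -2.35, -2.27 and -2.33. The other falls named were those of AT4G22485, BEE3, AT5G55050 and EXL5, at log2 -2.66 to -2.24. ADH1, AT5G10040, AT4G10270, SRO4, NIP2;1, AT5G57760 and AT5G55050 overlap another annotated gene. PDC1, NIP2;1 and AT4G22485 had 1.54, 2.199 and 2.03 times as many reads in the multi columns. All of these values are uncertain to that extent, as is that of MBF1C below, which overlaps another gene.

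Of the 51 core anaerobic genes, known to rise under low oxygen, 44 rose in total mRNA over all genes tested and 48 adjusted over the list alone (median log2 +3.89, camera adjusted p = 1.1e-118). Of the 29 glycolysis and fermentation enzymes 9 rose (10 adjusted over the list alone): ADH1, PDC1, PDC2, SUS1, SUS4, the phosphofructokinases PFK3 and PFK6, the alanine aminotransferase AlaAT1 and AT4G17260. The median of that list was log2 +0.30 and its mean +1.49, and its adjusted p of 6.81e-13 became adjusted p = 0.0563 with an estimated correlation. Among 25 early stress regulators 9 rose (18 adjusted over the list alone, 5 after scaling, median log2 +2.123, adjusted p = 9.27e-27), including the NADPH oxidase RBOHD (log2 +4.00 ± 0.40) and WRKY70 (log2 +3.62 ± 0.53). Among 25 ethylene and oxygen sensing genes 6 rose and 1 fell (6 and 3 adjusted over the list alone). The ACC oxidase ACO1 (AT2G19590) rose by log2 +3.89 ± 0.27 and the ethylene receptor ETR2 by +2.02 ± 0.35, and the receptor ERS1 fell by log2 -1.78 ± 0.25. The list had a median of log2 +0.07 and an adjusted p of 0.00385, which became adjusted p = 0.0721 with an estimated correlation. DREB2A (log2 +2.31 ± 0.38) and MBF1C (log2 +1.86 ± 0.35) rose among 19 heat shock proteins and factors (10 adjusted over the list alone, median log2 +1.23, adjusted p = 1.15e-14). JAZ3 (log2 +2.44 ± 0.37) and JAZ8 (log2 +1.85 ± 0.35), repressors of jasmonate signalling, rose among 10 jasmonate genes (2 adjusted over the list alone, median log2 +0.48, adjusted p = 0.000254). With an estimated correlation, core anaerobic genes had camera adjusted p = 0.00429 and early stress regulators 0.0174. Heat shock genes had 0.00859 and jasmonate genes 0.0262. The glycolysis, ethylene, early stress and jasmonate lists share members with the core anaerobic list, so their rises are not independent of it in any pool.

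Root-enriched genes were lower in total mRNA as a list (median log2 -0.95 over 12 genes, camera adjusted p = 5.51e-07), which became adjusted p = 0.0879 with an estimated correlation. EXPA18 and SHV2 (log2 -2.05 ± 0.34) fell among them (5 adjusted over the list alone). No sugar starvation gene was called (0 of 16, 0 adjusted over the list alone). The list had a median of log2 +0.47 and an adjusted p of 0.0127, which became adjusted p = 0.533 with an estimated correlation and 0.0601 after scaling. The 72 cytosolic ribosomal proteins (median log2 +0.02, adjusted p = 0.296), 18 translation factors (-0.16, 0.148), 48 nuclear photosynthesis genes (+0.16, 0.155), 21 cell wall and aquaporin genes (-0.11, 0.428), 22 histones and cell cycle genes (+0.11, 0.288), 13 circadian clock genes (-0.08, 0.664), 14 known uORF genes (-0.31, 0.103) and 8 reference genes (-0.02, 0.803) did not pass the list test. For the ribosomal proteins the mean (-0.05) and the test pointed down, and for the clock genes the mean (+0.02) and the test pointed up. The count of 237 calls fell to 76 without normoxia library 1, 70 without hypoxia library 1, 72 without normoxia library 2 and 111 without hypoxia library 2. HRE1, AT5G57760, RHS12 and BEE3 passed in none of these 4 fits, and HRE1, AT5G57760 and BEE3 had adjusted p of 0.0655, 0.0935 and 0.155 after median-of-ratios scaling.

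**Figure D1:**
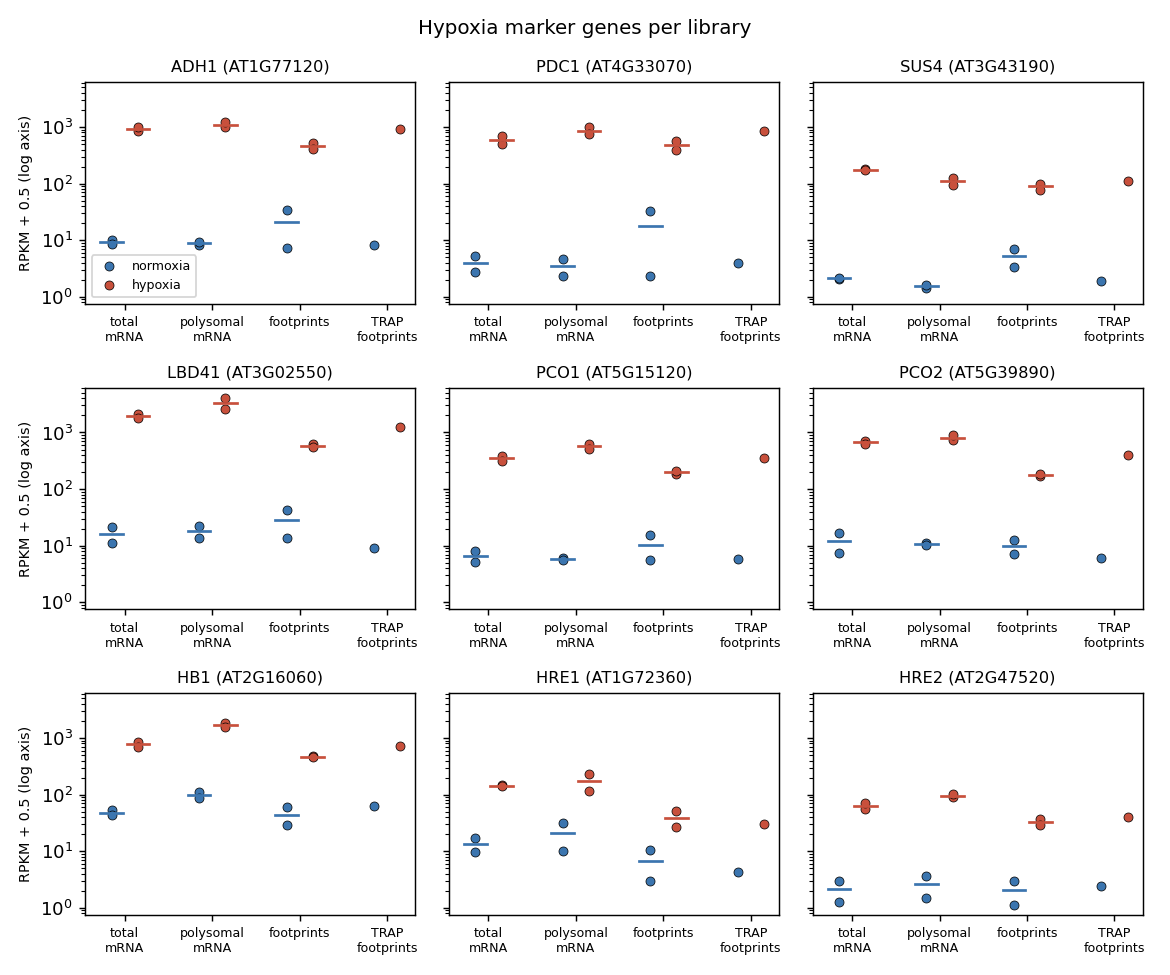
RPKM + 0.5 (log axis) of 9 hypoxia marker genes in each library of total mRNA, polysomal mRNA, conventional footprints and TRAP footprints, with points for single libraries and bars for the mean of 2. Hypoxia libraries lie above normoxia libraries for each of the 9 genes in each pool, and ADH1 reaches 33.3 RPKM in footprint normoxia library 1 against 6.90 in library 2.

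The second comparison asks which transcripts changed on tagged polysomes. ADH1, PDC1, SUS4, LBD41, PCO1 and PCO2 rose here too. AT5G10040 (log2 +9.45 ± 0.57) and AT4G10265 (log2 +8.97 ± 0.59) led them. PDC1 went from 3.01 ± 1.60 to 859 ± 171 RPKM (n = 2, log2 +8.22 ± 0.91, limma adjusted p = 0.00109) and ADH1 from 8.29 ± 0.90 to 1096 ± 148 RPKM (log2 +7.18 ± 0.53). LBD41 reached 3340 ± 1040 RPKM from 17.8 ± 6.21 (log2 +7.74 ± 0.50). BEE3, a transcription factor of brassinosteroid response, fell by log2 -3.54 ± 0.56.

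In polysomal mRNA 272 genes were called higher and 148 lower, a share of 64.8% higher. After median-of-ratios scaling 374 were higher and 104 lower, a share of 78.2%. Of the calls 250 higher and 71 lower genes were in both fits. The other large rises were those of AT4G10270, AT2G17850, CML38, SRO4 and AT4G33560, at log2 +6.90 to +7.96. SUS4 rose by log2 +6.37 ± 0.34, PCO1 by +6.81 ± 0.41, PCO2 by +6.43 ± 0.39, HB1 by +4.32 ± 0.34, HRE2 by +5.56 ± 0.55 and HRE1 by +3.43 ± 0.66. The largest fall was that of AT5G57760 (log2 -4.77 ± 0.67), an uncharacterized protein. The phosphatase AT5G02760 fell by log2 -3.18 ± 0.62, the transcription factor NAC6 by -3.14 ± 0.47, the SAUR-like AT3G53250 by -2.95 ± 0.62 and the homeobox gene HB5 by -2.49 ± 0.42. GTE7, AT1G23030, XTH8 and AT5G04800 fell by log2 -2.30, -2.27, -2.21 and -2.19. AT5G04800 had 6.83 times as many reads in the multi columns, and its value is uncertain, as are those of AT5G02760 and GTE7, which overlap another gene.

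Core anaerobic genes rose on polysomes in 43 of 51 cases (48 adjusted over the list alone, median log2 +4.29, camera adjusted p = 7.99e-85). The 9 glycolysis and fermentation enzymes that rose in total mRNA rose here as well (12 of 29 adjusted over the list alone, median log2 +0.79, adjusted p = 1.87e-20), with PFK6 at log2 +4.09 ± 0.25. Of 25 early stress regulators 12 rose (19 adjusted over the list alone, median log2 +2.08, adjusted p = 4.73e-23), among them RBOHD (log2 +4.43 ± 0.40), WRKY70 (+4.64 ± 0.53) and the kinase MPK3 (+1.71 ± 0.26). Among 25 ethylene and oxygen sensing genes 6 rose and 3 fell (9 and 4 adjusted over the list alone, median log2 +0.47, adjusted p = 6.36e-05). The falls were those of the receptors ERS1 (log2 -1.55 ± 0.25) and ERS2 (-1.83 ± 0.39) and of the kinase CTR1 (-1.10 ± 0.30), all parts of ethylene signalling. HSP70 (log2 +1.94 ± 0.25), HSP90.1 (+2.19 ± 0.33), HSP101 and DREB2A (+2.96 ± 0.38) rose among 19 heat shock genes (11 adjusted over the list alone, median log2 +1.38, adjusted p = 6.65e-12). JAZ3 (log2 +3.00 ± 0.37) and JAZ8 (+2.89 ± 0.35) rose among 10 jasmonate genes (2 adjusted over the list alone, median log2 +0.69, adjusted p = 6.36e-05). With an estimated correlation, the lists of this paragraph had camera adjusted p from 0.0108 (core anaerobic genes) to 0.0215 (ethylene and oxygen sensing).

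Cytosolic ribosomal proteins were lower on polysomes, with 67 of 72 members below the median gene (median log2 -0.65, camera adjusted p = 1.13e-15, and 0.024 with an estimated correlation). AT1G27400 (log2 -1.05 ± 0.25), RPL16B (-1.02 ± 0.25, with 1.52 times as many reads in the multi columns) and PGY1 (-0.99 ± 0.26) fell over all genes tested and 46 members fell adjusted over the list alone. After scaling 0 members passed in limma, and the list kept an adjusted p of 1.02e-11. Sugar starvation genes had a median of log2 +0.69 with 0 of 16 called (0 adjusted over the list alone), and an adjusted p of 0.00376, which became adjusted p = 0.378 with an estimated correlation. The cell wall and aquaporin genes had a median of log2 +0.51 with 0 of 21 called (0 adjusted over the list alone), and an adjusted p of 0.0461, which became adjusted p = 0.378 with an estimated correlation and 0.0996 after scaling. RAT5, a histone H2A, rose by log2 +1.55 ± 0.28 (adjusted p = 0.0506 after scaling) in a list that did not pass (22 histones and cell cycle genes, median +0.28, adjusted p = 0.206). Translation factors (median log2 -0.02, adjusted p = 0.135), nuclear photosynthesis genes (+0.11, 0.25), root-enriched genes (-0.11, 0.537), circadian clock genes (+0.06, mean -0.03, 0.941), known uORF genes (-0.33, 0.135) and reference genes (-0.22, 0.109) did not pass either. The count of 420 calls moved to 129 without normoxia library 1, 126 without hypoxia library 1, 176 without normoxia library 2 and 2083 without hypoxia library 2, where most calls were lower (404 higher and 1679 lower). GTE7 and AT3G53250 passed in 1 of these 4 fits, and AT5G02760 and HRE1 in 2, with adjusted p of 0.0587 and 0.053 after scaling.

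The third comparison asks which transcripts changed in the ribosome footprints. Footprints rose on ADH1, PDC1, SUS4, LBD41, PCO1 and PCO2 and fell on 54 of 72 ribosomal protein transcripts, or 14 after scaling. ADH1 went from 20.1 ± 18.7 to 464 ± 80.7 RPKM (n = 2, log2 +5.36 ± 0.53, limma adjusted p = 0.00223) and PDC1 from 17.0 ± 21.5 to 471 ± 116 RPKM (log2 +6.23 ± 0.91). Normoxia library 1 had 33.3 and 32.2 RPKM of these 2 genes and library 2 had 6.90 and 1.81. Without library 1 the rises were log2 +6.50 and +8.19, and without library 2 they were +4.25 and +4.30, and all passed. HRA1 (AT3G10040), a transcription factor that restrains the hypoxia response, rose by log2 +5.39 ± 0.63. MTO3, an S-adenosylmethionine synthetase, fell from 543 ± 109 to 80.3 ± 18.9 RPKM (log2 -2.26 ± 0.28, adjusted p = 0.00158).

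Footprints were called higher on 300 genes and lower on 2182, a share of 12.1% higher. After median-of-ratios scaling 612 were higher and 377 lower, a share of 61.9%, and 288 higher and 377 lower genes were in both. Plastid genes took 52.2 ± 2.61% of the coding reads of hypoxic footprints and 24.8 ± 0.78% of those of normoxic footprints (n = 2). Organelle genes held 48.6 and 47.3% of aligned reads in the hypoxia libraries and 33.8 and 29.5% in the normoxia libraries. A larger organelle share lowers every nuclear RPKM, so the split as deposited does not measure how many genes fell. How much of the median shift it makes up was not tested. The other largest rises were those of AT2G17850, AT5G66985, NIP2;1, SRO4, AT5G10040, CML38 and AT3G27220, at log2 +5.23 to +6.26. LBD41 rose by log2 +5.06 ± 0.50, SUS4 by +4.68 ± 0.34, PCO1 by +4.90 ± 0.41, PCO2 by +4.70 ± 0.39, HB1 by +3.98 ± 0.34, HRE2 by +4.65 ± 0.55 and HRE1 by +3.20 ± 0.66. The largest falls were those of BEE3 (log2 -3.61 ± 0.56), AT5G02760 (-3.32 ± 0.62) and FLS2 (AT5G46330, -2.39 ± 0.39). XTH31, AT3G06070, MYB70, the acyl-CoA-binding protein ACBP6, the histone HTA11 and AT4G24275 fell by log2 -2.23 to -2.10. Without normoxia library 1 the rises of AT2G17850, AT5G66985, NIP2;1, SRO4, AT5G10040, CML38, AT3G27220, HRA1, LBD41, PCO1, HRE1, HRE2 and WRKY70 were larger by over 1.5 times, up to log2 +8.77 for AT5G66985. All 10 of these falls passed after scaling too. MTO3, AT5G02760, NIP2;1, SRO4, AT5G10040 and ADH1 overlap another gene and are uncertain.

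Core anaerobic genes rose in footprints in 45 of 51 cases (48 adjusted over the list alone, median log2 +3.53, camera adjusted p = 1.17e-77), and AT5G04120 fell (log2 -1.28). After scaling 46 rose and 0 fell. The same 9 glycolysis and fermentation enzymes rose, and 8 others fell (9 and 12 adjusted over the list alone). The fallers include the enolase LOS2 (log2 -0.77 ± 0.35) and the triose phosphate isomerase TPI (-0.71), and none passed after scaling (10 higher, 0 lower). The median of that list was log2 -0.07, its mean +1.03 and its test pointed up with an adjusted p of 0.00161, which became adjusted p = 0.276 with an estimated correlation. Early stress regulators rose in 9 of 25 cases (15 adjusted over the list alone, median log2 +1.85, adjusted p = 1.42e-17), with RBOHD at log2 +3.66 ± 0.40 and WRKY70 at +3.06 ± 0.53. TCH2, a calmodulin-like gene of that list, fell by log2 -0.43 before scaling and did not pass after it. Among 25 ethylene and oxygen sensing genes 6 rose and 3 fell (7 and 4 adjusted over the list alone, median log2 +0.19, adjusted p = 0.00541), which became adjusted p = 0.0936 with an estimated correlation. The falls of ERS1 (log2 -0.96), ERS2 (-1.17) and RAP2.12 (-0.47) did not pass after scaling. HSP101 (log2 +1.99 ± 0.35), HSFA7A (+1.82 ± 0.33) and DREB2A (+2.04 ± 0.38) rose among 19 heat shock genes (3 adjusted over the list alone, 5 after scaling, median log2 +1.10, adjusted p = 1.41e-09). JAZ3 (log2 +2.31 ± 0.37) and JAZ8 (+2.45 ± 0.35) rose and AOS fell (-0.43 ± 0.26, not after scaling) among 10 jasmonate genes (2 and 2 adjusted over the list alone, median log2 +0.36, adjusted p = 0.0137), which became adjusted p = 0.0936 with an estimated correlation. By the same estimate, core anaerobic genes had camera adjusted p = 0.0138, early stress regulators 0.0369 and heat shock genes 0.0281.

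Cytosolic ribosomal proteins fell in footprints in 54 of 72 cases (64 adjusted over the list alone, 14 after scaling), with a median of log2 -0.87 and a camera adjusted p of 3.36e-20, or 0.0295 with an estimated correlation. AT3G60770 (log2 -1.48 ± 0.24) and UBQ1 (-1.45 ± 0.25, with 1.73 times as many reads in the multi columns) passed after scaling, and emb2386 (-1.35 ± 0.32) had an adjusted p of 0.123 there. Translation factors fell in 7 of 18 cases (12 adjusted over the list alone, 2 after scaling, median log2 -0.63, adjusted p = 0.000227), which became adjusted p = 0.178 with an estimated correlation. They include LOS1, elongation factor 2, at log2 -0.83 ± 0.23, and AT5G60390, an elongation factor 1-alpha with 3.42 times as many reads in the multi columns, at -1.14 ± 0.24. Known uORF genes, whose leaders hold a known upstream reading frame, had a median of log2 +0.92 over 14 genes (adjusted p = 0.00125). That value became adjusted p = 0.178 with an estimated correlation and adjusted p = 0.839 over all exons. In that list bZIP2 rose (log2 +2.32 ± 0.39), and XPL1 (-1.01 ± 0.38) and MP (-0.68 ± 0.33) fell before scaling and not after (3 up and 2 down adjusted over the list alone, 3 up and 0 down after scaling). HSP101, UBQ1, bZIP2 and XPL1 overlap another gene and are uncertain. Cell wall and aquaporin genes fell in 6 of 21 cases (13 adjusted over the list alone, 0 after scaling, median log2 -0.61, adjusted p = 0.00541), which became adjusted p = 0.189 with an estimated correlation. EXPA18, PHT1;4 (log2 -0.95 ± 0.28) and SHV2 (-1.15 ± 0.34) fell among 12 root-enriched genes (4 adjusted over the list alone, 1 after scaling, median log2 -0.63, adjusted p = 0.014), which became adjusted p = 0.3 with an estimated correlation. Sugar starvation genes had a median of log2 +0.73 with 0 of 16 called (0 adjusted over the list alone, adjusted p = 0.00362), which became adjusted p = 0.281 with an estimated correlation.

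Nuclear photosynthesis genes (median log2 -0.44, adjusted p = 0.181), histones and cell cycle genes (-0.30, 0.065), circadian clock genes (+0.24, 0.257) and reference genes (-0.25, 0.145) did not pass the list test in footprints. The photosynthesis genes PSAK, PSBO2, PSBQ-2, FNR1 and ATPD and the histone H3 and H4 genes AT1G09200, AT5G59690, AT5G65360, AT5G10390 and AT5G10400 fell before scaling and not after it. AT5G59690, AT5G10390 and AT5G10400 had 7.41, 1.98 and 2.115 times as many reads in the multi columns and FNR1 overlaps another gene, so these are uncertain. GRP7, an RNA-binding protein of the clock, fell in both fits (log2 -1.56 ± 0.38). The count of 2482 calls moved to 324 without hypoxia library 1, 182 without hypoxia library 2, 1109 without normoxia library 1 and 220 without normoxia library 2, and to 302 in the multi columns (230 higher, 72 lower). XTH31 and AT3G06070 passed in none of these 4 fits, and the root-enriched and the cell wall lists had adjusted p of 0.0553 and 0.0823 without normoxia library 1.

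**Figure D2:**
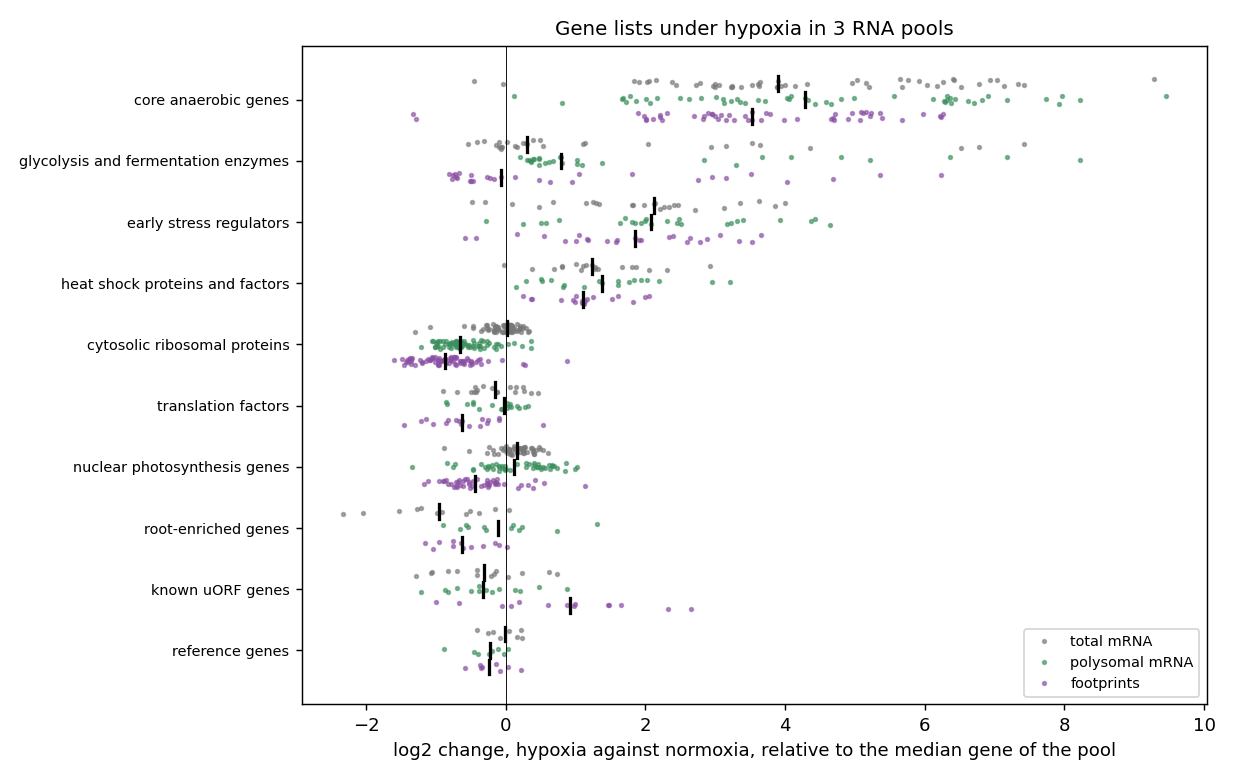
Log2 change (hypoxia against normoxia, relative to the median gene of the pool) of each member of 10 gene lists, with dots for genes and black bars for list medians, in total mRNA, polysomal mRNA and conventional footprints. Core anaerobic genes have medians of +3.89, +4.29 and +3.53 in the 3 pools, and cytosolic ribosomal proteins +0.02, -0.65 and -0.87.

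The hypoxia response was then compared across the 3 pools. Of 421 genes called higher in any pool 135 were called in all 3, 63 in 2 and 223 in 1, and of 2243 called lower 16, 110 and 2117. Higher in both total and polysomal mRNA were 156 genes, where independent lists would share 2.65. Total mRNA and footprints shared 150 (2.92 for independent lists), and polysomal mRNA and footprints 162 (4.36). Lower calls were shared by 17 (0.435), 42 (6.42) and 99 genes (17.3) in the same order. After median-of-ratios scaling 145 of 785 genes were higher in all 3 pools and 542 in 1, 6 of 477 were lower in all 3 and 432 in 1, and the shared lower calls were 10, 20 and 27. Over 18701 genes, which are not independent replicates, the log2 changes of total and polysomal mRNA had Pearson r 0.636 and Spearman rho 0.391. Total mRNA and footprints had r 0.596 and rho 0.425, and polysomal mRNA and footprints r 0.486 and rho 0.299. These pairs of contrasts share no library.

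Whether ribosome loading changed beyond mRNA abundance was asked with interaction terms in the same fit. Footprints on cytosolic ribosomal protein transcripts changed by log2 -0.85 against their total mRNA (median of 72, 67 of 72 below the median gene, camera adjusted p = 1.23e-25). The list passed with an estimated correlation (adjusted p = 0.0475), and 45 of its members passed adjusted over the list alone and 0 over all genes. On polysomes the same list had a median of log2 -0.71 against total mRNA (adjusted p = 9.72e-16), which became adjusted p = 0.152 with an estimated correlation. Known uORF genes lay the other way, at a median of log2 +1.35 for footprints over total mRNA (13 of 14 positive, adjusted p = 8.13e-07), which became adjusted p = 0.172 with an estimated correlation and adjusted p = 0.737 over all exons. Core anaerobic genes had a median of log2 -0.73 for footprints over total mRNA (adjusted p = 4.48e-05), which became adjusted p = 0.466 with an estimated correlation and adjusted p = 0.5 without footprint normoxia library 1. Glycolysis and fermentation enzymes had a median of log2 +0.44 for polysomal over total mRNA (adjusted p = 7.07e-05) and -1.02 for footprints over polysomal mRNA (adjusted p = 3.49e-10), which became adjusted p = 0.405 and adjusted p = 0.202 with an estimated correlation. For polysomal over total mRNA, root-enriched genes (median log2 +0.66, adjusted p = 5.25e-05) and cell wall and aquaporin genes (+0.47, 0.00992, and 0.0696 after scaling) each became adjusted p = 0.405 with an estimated correlation. For footprints over total mRNA, glycolysis enzymes (-0.45, 4.48e-05), translation factors (-0.50, 0.0014) and cell wall genes (-0.45, 0.00775) each became adjusted p = 0.305 with an estimated correlation. Histones (-0.56, 0.00284), photosynthesis genes (-0.59, 0.0212) and root-enriched genes (+0.29, 0.0478) became adjusted p = 0.248, adjusted p = 0.674 and adjusted p = 0.613 with an estimated correlation. For footprints over polysomal mRNA, cell wall genes (-1.03) and known uORF genes (+1.297), both at 3.55e-05, became adjusted p = 0.202 with an estimated correlation. Core anaerobic genes (-0.89, 8.17e-05), ribosomal proteins (-0.30, 0.00114) and translation factors (-0.27, 0.0141) became adjusted p = 0.384, and histones (-0.59, 0.00918) adjusted p = 0.267, with an estimated correlation. Over all exons in place of the CDS, known uORF genes had an adjusted p of 0.278 for footprints over polysomal mRNA. Histones had adjusted p values of 0.805 for footprints over total mRNA and 0.568 over polysomal mRNA. Root-enriched genes had an adjusted p of 0.052 for footprints over total mRNA, and ribosomal proteins and translation factors 0.392 and 0.0833 for footprints over polysomal mRNA. Without footprint normoxia library 1, core anaerobic genes had an adjusted p of 0.236 for footprints over polysomal mRNA. For footprints over total mRNA cell wall genes had 0.203, photosynthesis genes 0.5 and root-enriched genes 0.108 without that library.

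By gene, PME2 (AT1G53830, chromosome 1, 20098522 to 20100889), a pectin methylesterase, passed in the interaction of footprints over polysomal mRNA (log2 -3.57 ± 0.43 SE, limma adjusted p = 0.0474). Its footprints went from 16.1 ± 0.49 to 5.23 ± 1.18 RPKM and its polysomal mRNA from 2.74 ± 0.63 to 15.4 ± 0.41 RPKM (n = 2). It had an adjusted p of 0.0623 after scaling and passed in none of the 8 fits with 1 library left out. For polysomal over total mRNA limma called 0 genes, with 868 at an unadjusted p under 0.05, where 935 are due by chance, and limma-voom called 0. For footprints over total mRNA limma called 0, with 1885 at an unadjusted p under 0.05, and limma-voom called 0. For footprints over polysomal mRNA 1 was called, with 2507 at an unadjusted p under 0.05, and limma-voom called 1 with the deposited denominators and 0 with scaling. After median-of-ratios scaling, 1245, 1331 and 2519 genes had an unadjusted limma p under 0.05 in the same order of interactions. All these fits leave the replicate number out. Entering it as a block raised the calls of both footprint interactions, as given below with the processing settings. Lists passed with the preset correlation numbered 4, 9 and 7 of 16 in these 3 interactions, and with an estimated correlation 0, 1 and 0. The simulated interaction of polysomal over total mRNA recovered 0% of genes changed 4-fold, so gene-level differences of that size were not detectable there.

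Next, the pools were compared with each other in normoxia. The pools also differ in library protocol, and pool and protocol cannot be told apart in these contrasts. The list tests in this comparison were chosen after its gene calls were seen. The root hair genes RHS12, RHS18 and RHS19 were low on tagged polysomes against total mRNA and high in footprints against polysomal mRNA. In polysomal over total mRNA the root hair gene RHS18 stood at log2 -4.06 ± 0.46 (limma adjusted p = 0.00158), AT4G22485 at -4.16 ± 0.44 and the peroxidase AT1G30870 at -3.96 ± 0.39. The 12 root-enriched genes had a median of log2 -2.18 there with 6 called lower (camera adjusted p = 7.44e-08), which became adjusted p = 0.202 with an estimated correlation. The tagged gene RPL18 was higher on polysomes by log2 +2.21 ± 0.34 (adjusted p = 0.00921, and 0.0525 after scaling).

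In polysomal over total mRNA 10 genes were called higher and 377 lower. Besides RPL18, the rises named were AT3G11930, AT1G09310, the defensin-like AT3G05730 and the lipid transfer protein LP1, at log2 +1.58 to +1.88, and the other falls were AT5G57625 and AT2G31141, at -4.00 and -3.93. AT2G31141 had 4.29 times as many reads in the multi columns and is uncertain. Histones and cell cycle genes had a median of log2 +0.49 (adjusted p = 0.000288), which became adjusted p = 0.202 with an estimated correlation. Cytosolic ribosomal proteins (+0.20), early stress regulators (+0.34) and nuclear photosynthesis genes (+0.42) each had an adjusted p of 0.0178, which became adjusted p = 0.741 with an estimated correlation. The count of 387 calls went to 130 without total library 1, 79 without polysomal library 1 and 44 without total library 2.

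Footprints over total mRNA gave 62 higher and 1888 lower genes in normoxia, a share of 3.18% higher, and 125 and 262 after scaling, a share of 32.3%. The rises included the proline-rich extensin-like genes AT2G43150 (log2 +3.75 ± 0.65), AT3G28550 (+3.58 ± 0.63) and AT3G54580 (+3.30 ± 0.49), which have 1.51, 6.15 and 6.39 times as many reads in the multi columns and are uncertain, and AT1G31835 (+4.39 ± 0.72) and AT1G80450 (+3.72 ± 0.75). The falls named were AT5G47435 (log2 -4.59 ± 0.36, overlapping another gene), AT4G32240, AT1G58150, AT3G54880 and AT2G27402 (2.69 times as many reads in the multi columns), at -4.20 to -3.88. Core anaerobic genes had a median of log2 +0.68 (adjusted p = 1.06e-06), which became adjusted p = 0.694 with an estimated correlation. Without footprint library 1 their median was log2 -0.01 (adjusted p = 0.805). Known uORF genes had a median of log2 -1.06 with 7 of 14 called lower (adjusted p = 0.00149), which became adjusted p = 0.588 with an estimated correlation. Histones and cell cycle genes had a median of log2 +0.47 (adjusted p = 0.00308), which became adjusted p = 0.588 with an estimated correlation. The count of 1950 went to 479 without footprint library 2, 38 without total library 1 and 259 without total library 2.

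Footprints over polysomal mRNA gave 712 higher and 3294 lower genes, a share of 17.8% higher, and 1431 and 1170 after scaling, a share of 55.0%. The rises were led by AT3G28550 (log2 +5.76 ± 0.63), AT3G05727 (+5.69 ± 0.37), AT4G22485 (+5.68 ± 0.44), AT3G54580 (+5.64 ± 0.49) and AT2G43150 (+5.58 ± 0.65). The root-enriched genes had a median of log2 +2.43 with 8 higher and 1 lower (adjusted p = 1.45e-07), which became adjusted p = 0.434 with an estimated correlation. This contrast and that of polysomal over total mRNA share the polysomal libraries. The falls included the ribosomal protein L41 genes AT3G11120 (log2 -3.37 ± 0.38, with 1.74 times as many reads in the multi columns) and AT3G08520 (-3.33 ± 0.39, with 3.84 times as many reads in the multi columns), AT3G45160 and GLN1;5 (adjusted p = 0.0833 after scaling). BZIP53, a transcription factor whose leader holds a conserved uORF, stood at 12.4 ± 0.61 RPKM in footprints and 149 ± 43.2 RPKM in polysomal mRNA (log2 -3.07 ± 0.30), and it overlaps another gene. Known uORF genes had a median of log2 -1.27 with 8 of 14 called lower (adjusted p = 0.0231), core anaerobic genes +0.52 (adjusted p = 0.0205), and glycolysis and fermentation enzymes +0.46 (adjusted p = 0.0445), each of which became adjusted p = 0.813 with an estimated correlation. Without footprint library 1 these 3 lists had medians of log2 -0.81 (adjusted p = 0.153), -0.19 (0.926) and +0.40 (0.231). The count of 4006 went to 1734 without footprint library 2, 1519 without polysomal library 1 and 2226 without polysomal library 2.

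The position of footprints along transcripts was compared next. With plastid and mitochondrial genes left out, coding sequences held 67.5 ± 3.87% of the aligned reads of hypoxic footprints and 79.6 ± 2.64% in normoxia (n = 2). With these genes included the order turned, at 74.5 ± 1.16% in hypoxia and 72.6 ± 0.11% in normoxia. 3' UTRs held 10.5 ± 3.05% in hypoxia and 6.21 ± 1.84% in normoxia. Per 100 coding reads, the 3' UTRs had 11.9 and 19.6 reads in the hypoxia libraries and 6.02 and 9.65 in the normoxia libraries. In total mRNA 3' UTRs held 12.8 ± 1.26% in hypoxia and 13.6 ± 1.97% in normoxia. Where organelle genes were left out, organelle reads between genes stayed in the base, and a read can count for more than 1 feature. The values are therefore not exact parts of the nuclear reads. These shares were not tested.

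Footprints over 3' UTRs rose against the coding sequence of the same gene on 390 of 15250 intervals and fell on 11 (limma), with a median log2 ratio change of +1.03 and 87.5% of intervals above 0. The largest called changes lay on intervals of few bases: MAC3B (chromosome 2, 14126577 to 14126583, log2 +5.59 ± 0.79 SE), GAUT7 (+5.04) and PUB4 (+4.99) rose, and AT5G08060 (-5.04), AT2G11890 (-4.89) and LPPgamma (-3.83) fell. Limma estimated 1 common spread for all 3' UTR intervals, and with a pseudocount of 0.1 in place of 0.5 it called 0. The calls numbered 2 without hypoxia library 1, 2 without hypoxia library 2, 2061 without normoxia library 1 and 135 without normoxia library 2. For 5' UTRs limma called 0 of 17384 intervals, with 1041 at an unadjusted p under 0.05, and 1948 without normoxia library 1. For uORFs it called 0 of 939, with 73 at an unadjusted p under 0.05, and 139 without normoxia library 1. For introns it called 0 of 10078 in total mRNA, 0 of 9112 in polysomal mRNA and 0 of 14516 in footprints, with 93, 64 and 1283 at an unadjusted p under 0.05. No other tool was run on these ratios.

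**Figure D3:**
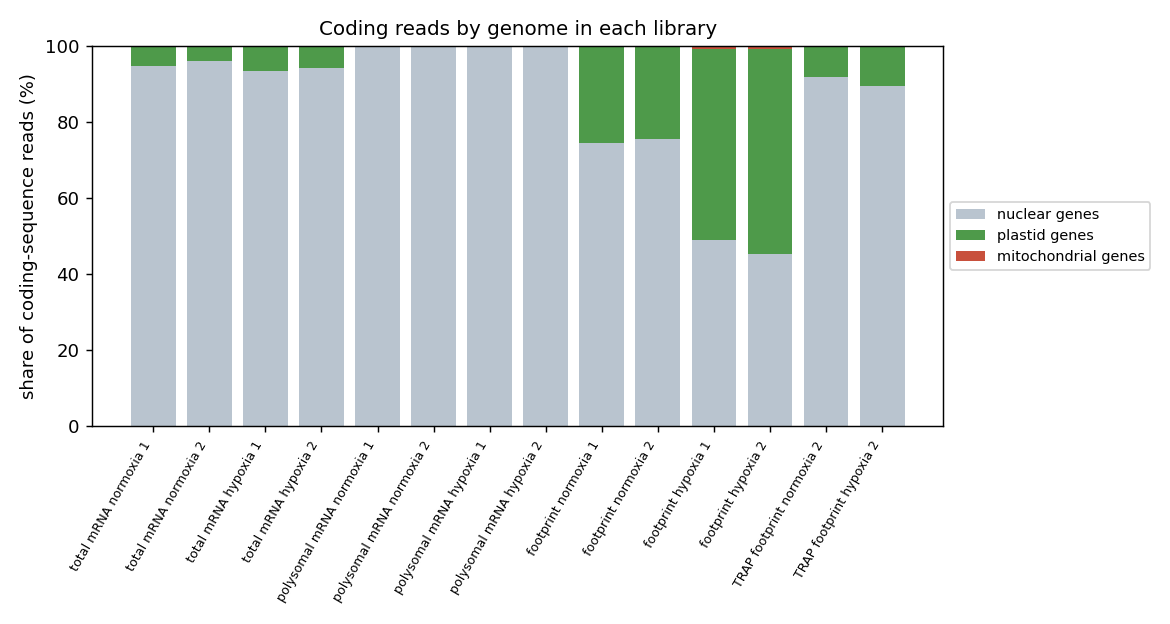
Share of coding-sequence reads (%) from nuclear, plastid and mitochondrial genes, as stacked bars for each of the 14 libraries. Plastid genes hold 52.2% on average in hypoxic conventional footprints, 24.8% in normoxic ones, and 10.3% and 8.21% in the TRAP footprint libraries.

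The last comparison set the TRAP footprints against the conventional footprints. With 1 TRAP library per condition it has no replicate check. Hypoxia marker genes were higher in the hypoxic TRAP library, with log2 changes of +6.71 for ADH1, +7.69 for PDC1, +5.79 for SUS4, +7.03 for LBD41, +5.90 for PCO1, +5.99 for PCO2, +3.49 for HB1, +3.98 for HRE2 and +2.74 for HRE1. Of the 300 genes called higher in conventional footprints 290 were higher in TRAP footprints too (median log2 +1.79, against +2.38 in conventional footprints). Of the 377 called lower in both scalings 344 were lower (median -0.72, against -1.28). Root hair genes were low in the normoxic TRAP library against conventional footprints: RHS18 at log2 -2.93, RHS19 at -2.91, RHS12 at -2.87 and EXPA18 at -2.59.

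Across genes, which are not independent replicates, TRAP and conventional footprints had Spearman rho 0.936 (Pearson r 0.937) in hypoxia over 17538 genes and rho 0.934 (r 0.932) in normoxia over 17941. The log2 changes of hypoxia had r 0.544 and rho 0.454. The median gene was at log2 +0.70 in hypoxia and +0.19 in normoxia, and the values given are relative to it. The root-enriched list had a median of log2 -1.39 in normoxia and -1.09 in hypoxia, at percentile 0.01 of 10000 random lists in each, the smallest they can give. In normoxia the core anaerobic list (log2 -0.59) and the glycolysis list (-0.40) were also at percentile 0.01, and the known uORF list (+0.73) was at percentile 99.97. Against footprint normoxia library 2 alone, a choice made after the values were seen, the core anaerobic list was at log2 +0.03 (percentile 28.4), so its low value was not seen there. The root-enriched list (-1.21, percentile 0.01), the glycolysis list (-0.27, 0.07) and the known uORF list (+0.69, 99.93) kept their direction. In hypoxia the core anaerobic list was at log2 -0.13 (percentile 0.47) and the histone and cell cycle list at -0.27 (0.52). The glycolysis list (+0.26, 77.6) and the known uORF list (+0.24, 79.2) were not extreme in hypoxia. The histone list was at +0.16 (75.4) in normoxia. Nuclear photosynthesis genes were at log2 -0.14 in hypoxia (percentile 0.02) and -0.09 in normoxia (0.24), but at +0.44 (98.88) against normoxia library 2 alone. Sugar starvation genes turned likewise in normoxia, from -0.21 (1.69) to +0.30 (85.9). Cytosolic ribosomal proteins went from 0.00 (2.09) to -0.04 (0.02), and translation factors stood at -0.19 (1.00) against library 2 alone. These percentiles describe 2 pairs of libraries and not the conditions.

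**Figure D4:**
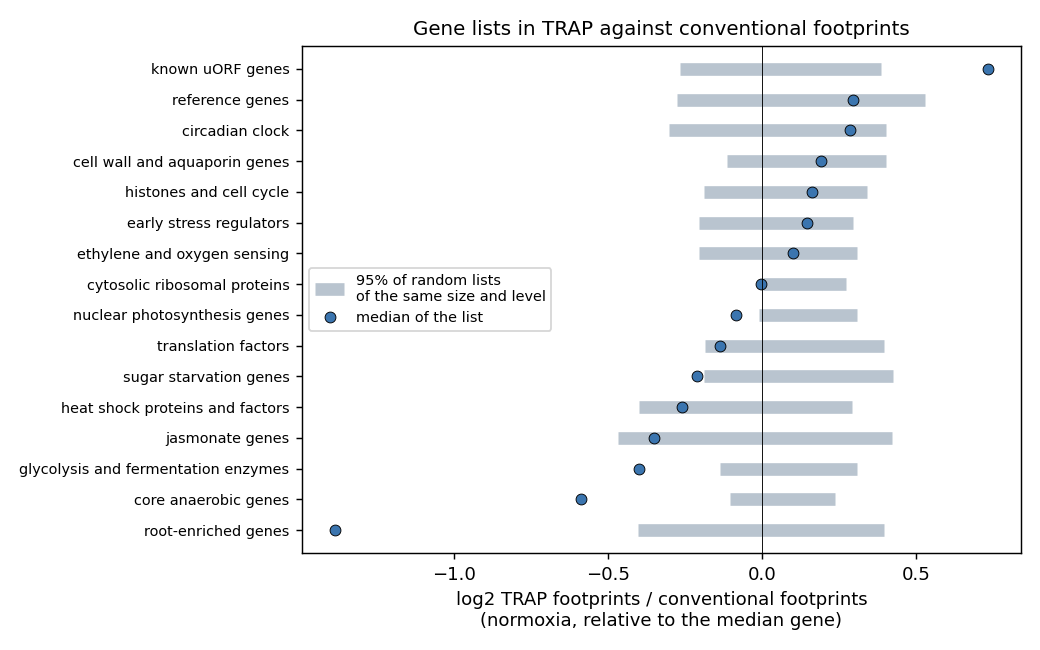
Median log2 ratio of TRAP over conventional footprints in normoxia, relative to the median gene, for each of 16 gene lists (points), with the range of 95% of random lists of the same size and level (bars). The root-enriched list lies lowest at -1.39, and the known uORF list highest at +0.73.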

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

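The tests of organelle reads and intergenic intervals in this part were chosen after the data were seen. PME2 was the 1 gene called for a hypoxia effect that differs between footprints and polysomal mRNA, at log2 -3.57 by the interaction term. It was not called after scaling, without the expression filter, in the compared pools alone or in the multi columns. Cytosolic ribosomal proteins differed between footprints and total mRNA as a list, with a median hypoxia effect of log2 -0.85 by the interaction term.

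Plastid genes, which the gene tests leave out, held 52.2 ± 2.61% of the coding reads of hypoxic conventional footprints (n = 2), 2.11 times the share in normoxia. They held 6.23 ± 0.52% in hypoxic total mRNA and 4.68 ± 0.91% in normoxic total mRNA. Total and polysomal mRNA were selected for poly(A) and footprints were not, so plastid and mitochondrial levels are not comparable between these pools. In the TRAP footprint libraries the share was 10.3% in hypoxia (95% Wilson interval 10.30 to 10.35) and 8.21% in normoxia (8.19 to 8.24). The gene with most plastid footprints, ATCG00490, held 8.64 ± 1.16% of coding reads in hypoxia and 5.64 ± 0.01% in normoxia. ATCG00020 held 7.15 ± 2.201% and 2.90 ± 0.67%. In the TRAP footprint libraries ATCG00020 alone held 6.40% in hypoxia and 6.29% in normoxia, most of the plastid share there. ATCG00490 held 0.93% and 0.63% in these 2 libraries. The TRAP plastid share thus rests largely on 1 gene. With organelle genes in the fit, limma called 27 of 73 plastid genes higher in footprints, 0 in total mRNA and 0 in polysomal mRNA, and 73, 64 and 72 of them stood above the median nuclear gene in the same order (median log2 +1.79, +0.36 and +1.02). Mitochondrial genes held 0.699 ± 0.02% of the coding reads of hypoxic footprints and 0.303 ± 0.07% in normoxia, and 17 of 33 were called higher. 3 tests of the plastid reads were run and then set aside after their results were seen, and no explanation is offered. They gave a rise of 2.27 times without the 3 genes with most reads, 1.33 times in total mRNA and 1.95 times in polysomal mRNA.

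Of 4403 intergenic intervals, 4 were called higher under hypoxia in all 3 pools. The interval between AT1G33360 and AT1G33370 (chromosome 1, 12096026 to 12097278) rose by log2 +5.47, +6.07 and +3.79 in total mRNA, polysomal mRNA and footprints. The intervals on chromosome 1 from 11972579 to 11975339 (+4.29, +4.40, +3.17), chromosome 3 from 10047344 to 10051611 (+3.66, +4.29, +2.69) and chromosome 4 from 6372771 to 6373096 (+5.27, +5.81, +2.204) lie beside AT1G33055, AT3G27220 and AT4G10265, which rose in all 3 pools too.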

How the results depend on the processing

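The settings chosen after the data were seen were limma-voom, the multi columns, the block with scaling, footprint normoxia library 1 left out with scaling, the 0.1 pseudocount of the feature tests, the TRAP lists against footprint normoxia library 2 alone, and the normoxia lists without library 1. The planned count tests with their own normalisation and filter were not run, since the files hold RPKM. Named genes were checked only in contrasts where the main fit called them, 168 pairs of gene and contrast. Over these pairs, 2460 of 2939 alternatives stayed past the threshold, 479 did not and 0 reversed direction. The pairs were called on the same libraries, so a reversal was unlikely from the start. Named genes that were not called were not checked. For called genes, the causes of the differences below were not tested, except that a fit with fewer libraries has fewer degrees of freedom.

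The replicate numbers were entered as a block. Same-numbered libraries deviated together with r 0.650 in total mRNA, 0.602 in polysomal mRNA and 0.342 in footprints, but with 2 pairs per pool they share only a number. The footprint titles carry other numbers (1 and 3 in hypoxia, 2 and 3 in normoxia), so which footprint libraries the block should pair is in doubt. With the block the calls were 1116 in total mRNA (531 higher, 585 lower), 4066 in polysomal mRNA (1228 higher, 2838 lower) and 7655 in footprints, so most calls were lower in total and polysomal mRNA too. For the interactions they were 0 for polysomal over total mRNA, 1400 for footprints over total mRNA and 2514 for footprints over polysomal mRNA. In normoxia they were 2219 for polysomal over total mRNA and 4730 for footprints over total mRNA. The feature tests gave 0 calls for 3' UTRs and 3 for polysomal introns with the block. Of 49 list calls 48 stayed with the block, among 52. With the block and scaling most calls were higher, at 953 in total mRNA (649 higher, 304 lower), 3369 in polysomal mRNA (2028 higher, 1341 lower) and 4104 in footprints (2147 higher, 1957 lower). The calls were then 3 and 1055 for the 2 footprint interactions, and 2187 for polysomal over total mRNA in normoxia (1364 higher, 823 lower).

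Scaling gave 989 calls in footprints, 0 for footprints over polysomal mRNA, 387 for footprints over total mRNA in normoxia and 2601 for footprints over polysomal mRNA in normoxia. Without footprint normoxia library 1, scaling gave 1004, 18, 517 and 2099 for the same results. The compared pools alone gave 107 calls in total mRNA, 70 in polysomal mRNA, 0 for footprints over polysomal mRNA, and 229 and 3058 for polysomal and footprints over total mRNA in normoxia. Limma-voom with scaling gave 1390 in footprints, 0 for footprints over polysomal mRNA, and 214 and 624 for polysomal and footprints over total mRNA in normoxia. With the deposited denominators limma-voom gave 182 for polysomal over total mRNA in normoxia. The multi columns gave 302 in footprints, 0 for footprints over polysomal mRNA, and 7624 and 9103 for footprints over total and polysomal mRNA in normoxia. No filter gave 0 for footprints over polysomal mRNA.

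With 1 library left out, the lone library of its group was assumed to vary like the other groups. The calls then ranged from 70 to 111 in total mRNA, 126 to 2083 in polysomal mRNA and 182 to 1109 in footprints. They ranged from 0 to 0, 0 to 1 and 0 to 1 for the interactions, the 1 of footprints over total mRNA arising without footprint normoxia library 2. In normoxia they ranged from 44 to 274 for polysomal over total mRNA, 38 to 1348 for footprints over total mRNA and 1519 to 2877 for footprints over polysomal mRNA. The ranges were 2 to 2061 for 3' UTRs, 0 to 1948 for 5' UTRs, 0 to 139 for uORFs and 0 to 0 for introns.

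3' UTR calls were 255 with a minimum of 5 reads and 0 with a pseudocount of 0.1. Of the 49 list calls 16 stayed with an estimated correlation and 41 over all exons. Fry, which tests whether the genes of a list move on balance 1 way, made 35 calls, of which 31 were the same list and direction. Without footprint normoxia library 1, sugar starvation genes passed in normoxia with the preset correlation, at adjusted p = 0.0455 for footprints over total mRNA and 0.0207 over polysomal mRNA. The correlations of hypoxia changes over called genes were 0.917 for total and polysomal mRNA, 0.853 for total mRNA and footprints, and 0.822 for polysomal mRNA and footprints. Over genes of at least 10 CPM the latter pairs had 0.686 and 0.571. TRAP and conventional footprints had rho 0.863 in hypoxia and 0.868 in normoxia over genes of at least 10 CPM, and 0.957 and 0.954 from 0.1 CPM. Leaving out organelle genes moved the coding share from 74.5% to 67.5% in hypoxic and from 72.6% to 79.6% in normoxic footprints. Other settings kept each count within 1.5 times the main one.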

Other observations

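The tests of footprint normoxia library 1 and of intron reads were chosen after their results were seen. In normoxia the bZIP transcription factors BZIP53, GBF6 and bZIP1 were high in TRAP footprints against conventional footprints, at log2 +1.40, +1.49 and +0.78 (1 library pair), and at +0.22, +0.13 and +0.26 in hypoxia. In known uORF genes, footprints over the uORF itself against the coding sequence were lower under hypoxia in 9 of 10 intervals. The change was log2 -2.19 ± 0.56 SE for BZIP53 and -2.11 ± 0.61 for bZIP44. Over the 939 uORFs with at least 10 reads in 2 or more libraries, 43.8% were higher, with a median of log2 -0.14. Some of the 10 rest on few reads, such as MP with 4 and 0 in hypoxia and 4 and 20 in normoxia. None of the 10 passed the test (limma adjusted p from 0.746 to 0.986 over uORFs with at least 1 read in 2 or more libraries).

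Footprint normoxia library 1 held more reads of hypoxia-raised genes than library 2. Of the 156 genes called higher in both total and polysomal mRNA, 132 were higher in library 1, by a median of log2 +0.51 (quartiles 0.15 and 1.41), where the normoxia libraries differed by a median of +0.16 in total mRNA and +0.30 in polysomal mRNA. If reads of a hypoxia library had been mixed in, the excess would be 1 fraction of the rise for all genes. It was 5.75% in 40 core anaerobic genes and 15.8% in 17 early stress regulators, a ratio of 2.75, whose 95% bootstrap interval of -0.96 to 4.17 leaves mixing open. A difference that follows the replicate number could also be the source, since hypoxia library 1 exceeded library 2 by a median of log2 +0.34 in the same genes; the bound for this test was rewritten after its result was seen, and it cannot be told apart from mixing. An uneven response among the normoxic seedlings was not tested.

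Footprints over 3' UTRs were higher against coding sequences under hypoxia, at a median of log2 +1.03. An effect of the pseudocount is argued against by the recovered reads, which gave a median of log2 +0.98 without a pseudocount over 8671 intervals with a mean of at least 30 reads. Reads from outside ribosomes, spread alike over introns and 3' UTRs, are argued against by the intron reads, whose log2 rise per coding read was 0.291 of that of the 3' UTR reads. Fragments of mature mRNA could still be a source, as could ribosomes past the stop codon, and neither was tested. In the TRAP footprints the 3' UTRs had 12.0 reads per 100 coding reads in hypoxia and 9.64 in normoxia (1 library each).

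Root genes were low in polysomal mRNA against total mRNA in normoxia, at a median of log2 -2.18 for the 12 root-enriched genes (camera adjusted p = 7.44e-08, and adjusted p = 0.202 with an estimated correlation). A candidate explanation is that fewer tagged ribosomes were recovered from the cells that express them. The TRAP footprints, captured by the same tag, had this list at percentile 0.01 of random lists against conventional footprints. Fewer ribosomes on these transcripts are argued against by the conventional footprints, where the list stood at log2 +0.33 over total mRNA. Footprint and total mRNA libraries differ in protocol too, and that contrast cannot separate protocol from ribosome number. The level of the tagged protein in these cells was not measured, so the first explanation remains a hypothesis.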
